A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

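Poly(A) RNA was measured in 18 libraries of Saccharomyces cerevisiae, 3 replicates in each of 6 groups. The groups cross 2 genotypes with 3 conditions: no stress at 30 °C, 15 min in 0.4 M NaCl, and 10 min at 39 °C. Per the labels, both strains are MATa cells in which LEU2 and TRP1 replace the chromosomal copies of HTA1-HTB1 and HTA2-HTB2, and a plasmid marked with HIS3 carries HTA1-HTB1. The wild-type plasmid encodes unchanged histone H2A and the mutant plasmid encodes H2A S121A, in which alanine replaces the serine. Groups were taken from the labels, and 0 columns were left without a sample.

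The values used are raw counts per gene, 1 column per library, deposited without normalization. The submitters' processing notes name TopHat2 2.0.1, featureCounts 1.4.6-p5 and DESeq2 1.10.1, with the builds sacCer3 and R64. The labels' protocols describe hot-phenol RNA, a stranded mRNA kit and paired-end sequencing. How strand and multiply mapped reads were treated, and whether reads or fragments were counted, is not given in the sources used here. Paralogs and overlapping genes are therefore named as uncertain in the text. The count table held 6746 features, of which 6025 matched the R64 reference table by locus tag, and coordinates are those of R64. Total counts ran from 39.6 to 53.03 M (mega) per library. A count of 3 corresponded to between 0.0566 and 0.0758 CPM, the counts of a gene scaled to a library total of 1 M, so low expression was resolved well below the CPM floor of 10 used for naming genes. PCR duplicates cannot be recognised in counts, so these floors cover counting error only.

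Counts were filtered with filterByExpr, which kept 6395 genes, and scaled by TMM in edgeR 4.0.16 under R 4.3.3. The features left out held 0.00142% of the counts. CPM values, log2 fold changes and their standard errors (SE) were computed from these counts. A robust quasi-likelihood model in edgeR with 1 mean per group was fitted to all 18 libraries, and each comparison was a contrast in it. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, two-sided. A response difference is the S121A response to a stress minus the wild-type (WT) response. Unless another method is named, each adjusted p for a gene is from this edgeR model. The SE of a log2 fold change is from this model too. It rests on a spread estimated over all 18 libraries, and not on the 3 libraries of each compared group alone.

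Gene names in the text follow a rule fixed before the data were examined. The gene lists, the models and tests of the comparisons, lists, scores and similarities, and the alternatives other than the 1 named as added below were fixed then too. The chromosome comparison and some tests of explanations were chosen afterwards. For each S121A against WT comparison, each WT stress response and heat against NaCl in WT, the rule takes the 10 largest log2 fold changes each way. These must have an adjusted p under 0.05, non-overlapping replicates and a mean CPM of at least 10 in the higher group. For each response difference it takes the 5 largest each way with the same p and CPM. It adds, per comparison, up to 4 members of each list with the largest change in either direction, and all members of the histone and strain marker lists.

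The 30 lists cover heat shock chaperones, osmotic stress genes, general stress genes, trehalose and glycogen, cytosolic ribosomal proteins, ribosome biogenesis, histones, strain markers, subtelomeric families, centromere and spindle checkpoint, DNA damage response, G1/S and G2/M cell cycle genes, and daughter and early G1 genes. They also cover a-specific genes, alpha-specific and silent mating genes, pheromone response, meiosis and sporulation, glucose-repressed genes, the iron regulon, the phosphate regulon, amino acid biosynthesis, methionine and sulfur, glycolysis, respiration, ergosterol synthesis, cell wall integrity, proteasome, unfolded protein response and oxidative stress. Lists were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the 30 lists of a comparison, and again with an estimated correlation. Camera compares a list with all other genes tested. Adjusted p for a list is from camera.

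Scores of stress-responsive genes are the mean of log2(CPM + 1) over genes whose average response in both genotypes was at least 2-fold. Their response difference was tested by an exact two-sided permutation of the genotype labels within each condition, with 400 arrangements and a smallest possible p of 0.005. Their SE combines the variances of the 4 groups over 3 libraries each, without matching replicate numbers. Chromosome levels were compared after the data were examined, as the median deviation of the chromosome's genes from their mean over libraries relative to the genes of other chromosomes. Genes with a mean of at least 8 CPM entered, and an exact permutation of genotype labels within conditions gave p, with 8000 arrangements and a smallest possible p of 0.00025. These chromosome p were adjusted over the 16 chromosomes.

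Replicate numbers were checked for pairing by correlating the deviations of same-numbered libraries from their group means. Only for S121A against WT under NaCl did every pair exceed 0.1, with r of 0.32, 0.12 and 0.21 across genes. The numbers may therefore pair these libraries, from the data and not from a statement in the labels. Single pairs reached 0.36 in S121A against WT without stress and -0.45 for NaCl against no stress in S121A, so such values do not establish pairing. The model without a replicate block was kept, and the block was an alternative.

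The same code was tested on simulated counts drawn from WT means and the real spread and library sizes. In each comparison 67, 67 and 66 genes were changed 1.5-, 2- and 4-fold. All groups were given the same spread per gene, and fewer genes were changed than were called in any real comparison. The shares recovered and false therefore hold for that setting, and do not give the error rates of the real counts. In the simulated S121A against WT comparison without stress, run on 6334 genes, 85.1% of genes changed 1.5-fold and 95.5% of those changed 2-fold were recovered, and 5.6% of calls were false. For the NaCl response difference 52.2% of 1.5-fold and 86.6% of 2-fold changes were recovered, with 10.9% of calls false. For the heat response difference the shares recovered were 43.3% and 86.6%, with 2.6% of calls false.

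Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, library totals alone, TMM without the stress and ribosome lists, no filter, a filter of 10 CPM in 3 libraries, the compared groups alone, a replicate block, an adjusted p under 0.01, another pseudocount of 0.25, score genes changed at least 4-fold and each library left out in turn. Leaving out chromosome III genes, those matched to the reference table, was added after the data were seen, and its list tests used the preset correlation alone.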

Results

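Messenger RNA was sequenced from WT yeast and from cells whose histone H2A carries S121A, a change at a conserved serine near the C-terminal tail. Each genotype was sampled 3 times without stress, 3 times after 15 min in 0.4 M NaCl and 3 times after 10 min at 39 °C. Total counts, in M (mega), were 45.4 to 49.1 in unstressed WT libraries and 47.03 to 53.03 in unstressed S121A. They were 44.8 to 47.0 in WT under NaCl and 43.1 to 44.6 in S121A under NaCl. Heated WT libraries held 42.9 to 50.1 and heated S121A libraries 39.6 to 47.6. The 10 most abundant genes held 13.5% to 15.9% of the counts in the libraries without heat and 18.3% to 22.4% in heated libraries. The first component of variation separated the libraries by stress and held 73.1% of the variance.

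HTA1 (YDR225W, chromosome IV, 915530 to 915928), the gene that carries the mutation, was expressed in every group. Its mean was 1003 ± 62.2 CPM in unstressed WT and 1081 ± 36.7 CPM in unstressed S121A (SD, n = 3), a log2 difference of 0.11 ± 0.10 that did not pass (adjusted p = 0.469) but did with library totals alone, at 0.28 (adjusted p = 0.0351). Under NaCl HTA1 was lower in S121A by a log2 fold change of -0.37 ± 0.10 (adjusted p = 0.00807), a difference that did not pass with the NaCl libraries alone (adjusted p = 0.0612) or without WT NaCl replicate 1 (adjusted p = 0.0609). Under heat the difference was -0.18 ± 0.10 (adjusted p = 0.155), and -0.24 with library totals alone (adjusted p = 0.0498). Its plasmid partner HTB1, which encodes H2B, differed by -0.06 ± 0.09 without stress (adjusted p = 0.682), and was lower in S121A by -0.46 ± 0.09 under NaCl and -0.59 ± 0.09 under heat. Counts per gene do not show the altered codon, so the expression of HTA1 does not check which libraries carry it. HTA2, deleted in both strains per the labels, was at 19.4 ± 1.28 CPM in unstressed WT and 21.5 ± 1.09 CPM in unstressed S121A, and reads shared with its paralog HTA1 cannot be separated here. HIS3, the marker on the plasmid, fell from 1065 ± 48.0 CPM in unstressed WT to 539 ± 46.2 CPM in unstressed S121A. Its log2 fold changes were -0.98 ± 0.10 without stress, -0.63 ± 0.10 under NaCl and -0.33 ± 0.10 under heat. The heat value of HIS3 did not pass when WT heat replicate 1, S121A heat replicate 1 or S121A heat replicate 2 was left out (adjusted p of 0.0569, 0.057 and 0.0713). LEU2, the marker that replaces HTA1-HTB1, differed by -0.15 ± 0.08 without stress (adjusted p = 0.177) and was higher in heated S121A by 0.31 ± 0.08, which did not pass with the heated libraries alone (adjusted p = 0.053). TRP1 differed by -0.09 ± 0.08 and URA3 by 0.32 ± 0.21 without stress, neither passing, and LYS2 was higher by 0.25 ± 0.08. That call ended in 4 of 6 cases with 1 library left out, with an adjusted p for LYS2 of 0.134 without WT no stress replicate 2. Among other histone genes HHF1 was the only one called without stress, at 0.48 ± 0.12. The histone list was not called in S121A against WT without stress (1 of 11 higher, 1 adjusted over the list alone; adjusted p = 0.373), under NaCl (4 lower, 4 adjusted over the list alone; adjusted p = 0.0744) or under heat (4 lower, 4 adjusted over the list alone; adjusted p = 0.0643). The 5 strain markers were not called as a list in any of these conditions, with adjusted p of 0.488, 0.474 and 0.914.

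Per the labels, the WT strain carries the same histone gene deletions and the same kind of plasmid as S121A, with the H2A sequence unchanged. Among genes meeting the naming rule, its glycerol importer gene STL1 rose most under NaCl. The log2 fold change was 13.25 ± 0.17 (SE, n = 3 per group), from a mean of 0.596 CPM. The transketolase gene TKL2 rose by 8.41 ± 0.12 and the glucose transporter gene HXT5 by 8.33 ± 0.14. Also higher were the aldehyde dehydrogenase gene ALD3 by 7.79 ± 0.10 and the cytosolic catalase gene CTT1 by 7.34 ± 0.10. Genes for making ribosomes fell, among them SYO1 by -6.59 ± 0.21, NOG2 by -6.21 ± 0.13, PUF6 by -6.07 ± 0.20, SPB1 by -5.91 ± 0.13 and NOC2 by -5.88 ± 0.14. All 22 osmotic stress genes rose, with a median log2 fold change of 5.08 (22 adjusted over the list alone; adjusted p = 2.26e-15, and adjusted p = 0.0308 with an estimated correlation). All 25 general stress genes rose, with a median of 3.85 (25 adjusted over the list alone; adjusted p = 1.02e-14, and adjusted p = 0.0322 with an estimated correlation). All 62 ribosome biogenesis genes fell, with a median of -3.80 (62 adjusted over the list alone; adjusted p = 1.8e-24, and adjusted p = 0.0322 with an estimated correlation). Of the G1/S genes 19 of 20 fell, including the DNA precursor enzyme gene RNR1 by -3.63 ± 0.10 and the cyclin gene CLB6 by -2.52 ± 0.23 (19 adjusted over the list alone; adjusted p = 3.8e-07, and adjusted p = 0.0308 with an estimated correlation).

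Other groups moved under NaCl by the preset test. Of 17 trehalose and glycogen genes 16 rose, led by PGM2 at 4.89 ± 0.10 and TPS2 at 4.59 ± 0.08 (16 adjusted over the list alone; adjusted p = 5.21e-10, but adjusted p = 0.107 with an estimated correlation). Cytosolic ribosomal protein genes fell in 132 of 138 cases with a median of -0.70 (133 adjusted over the list alone; adjusted p = 3.19e-13, but adjusted p = 0.37 with an estimated correlation). One called member of that list, RPP1, encodes a ribonuclease P subunit and not a ribosomal protein. Heat shock chaperones rose in 20 of 28 cases and fell in 3, with HSP26 up by 4.11 ± 0.10 and HSP42 by 4.07 ± 0.12 (20 and 3 adjusted over the list alone; adjusted p = 0.000161, but adjusted p = 0.37 with an estimated correlation). G2/M genes fell in 14 of 16 cases, including CLB1 by -2.54 ± 0.09 and CLB2 by -2.19 ± 0.08 (14 adjusted over the list alone; adjusted p = 0.000225, but adjusted p = 0.207 with an estimated correlation). Respiration genes rose in 30 of 44 cases and fell in 2 (30 and 2 adjusted over the list alone; adjusted p = 0.000361, but adjusted p = 0.37 with an estimated correlation). Oxidative stress genes rose in 15 of 21 and fell in 4, with TSA2 up by 2.81 ± 0.10 (15 and 4 adjusted over the list alone; adjusted p = 0.00939, but adjusted p = 0.37 with an estimated correlation). Of 6395 genes tested 4706 changed, 2324 higher and 2382 lower, of which 962 and 962 changed at least 2-fold.

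Heating WT cells induced the chaperones. HSP30, a plasma membrane stress protein, rose by a log2 fold change of 9.52 ± 0.14 (SE, n = 3 per group), the small heat shock protein gene HSP26 by 9.13 ± 0.13, the Hsp70 gene SSA4 by 8.14 ± 0.15, TMA10 by 8.47 ± 0.20 and SPI1 by 7.78 ± 0.13. AAH1, an adenine deaminase gene, fell most among genes meeting the naming rule, by -7.01 ± 0.14. It was followed by the ribosome assembly genes RRP5 at -6.55 ± 0.13 and ROK1 at -6.52 ± 0.19, the CTP synthase gene URA7 at -6.52 ± 0.11 and NOP7 at -6.43 ± 0.10. All 28 chaperone genes rose, with a median of 4.02 (28 adjusted over the list alone; adjusted p = 2.42e-14, but adjusted p = 0.0784 with an estimated correlation). All 25 general stress genes rose, with a median of 4.59 (25 adjusted over the list alone; adjusted p = 1.2e-12, and adjusted p = 0.0436 with an estimated correlation). All 62 ribosome biogenesis genes fell, with a median of -5.25 (62 adjusted over the list alone; adjusted p = 4.58e-23, and adjusted p = 0.0346 with an estimated correlation). Cytosolic ribosomal protein genes fell in 135 of 138 cases with a median of -2.41 (135 adjusted over the list alone; adjusted p = 1.51e-26, but adjusted p = 0.147 with an estimated correlation).

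Among the other groups in heated WT cells, unfolded protein response genes rose in 12 of 13 cases, including the endoplasmic reticulum Hsp70 gene KAR2 by 4.04 ± 0.08 and ERO1 by 3.45 ± 0.08 (13 adjusted over the list alone; adjusted p = 9.5e-05, and adjusted p = 0.0346 with an estimated correlation). Pheromone response genes fell in 13 of 16 cases and rose in 2, with FAR1 at -5.19 ± 0.09 and the transcription factor gene STE12 at -3.23 ± 0.10 (13 and 2 adjusted over the list alone; adjusted p = 0.00049, and adjusted p = 0.0346 with an estimated correlation). G1/S genes fell in 18 of 20 cases, including TOS6 by -4.28 ± 0.15 and CLN2 by -4.04 ± 0.11 (18 adjusted over the list alone; adjusted p = 4.64e-06, and adjusted p = 0.0346 with an estimated correlation). Proteasome genes rose in 32 of 33 cases, and the list includes their regulator RPN4 at 2.42 ± 0.07 (33 adjusted over the list alone; adjusted p = 2.63e-05, but adjusted p = 0.167 with an estimated correlation). The proteasome median was 0.59, or 0.21 with library totals alone. Amino acid biosynthesis genes fell in 39 of 42 cases, including LEU9 by -4.29 ± 0.10 and ILV3 by -4.25 ± 0.09 (39 adjusted over the list alone; adjusted p = 1.04e-09, but adjusted p = 0.167 with an estimated correlation). Osmotic stress genes rose in 21 of 22 cases with a median of 3.01 (21 adjusted over the list alone; adjusted p = 1.66e-09, but adjusted p = 0.0522 with an estimated correlation). In all, 5107 genes changed, 2595 higher and 2512 lower, with 1254 and 1360 changed at least 2-fold. Scaled by library totals alone, the split was 1760 higher and 3326 lower.

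Both stresses moved many of the same genes in WT. Called higher under both were 1880 genes, against 943 if the calls were independent, and called lower under both were 1893, against 936. Another 308 went opposite ways. Both comparisons share the 3 unstressed WT libraries, and simulated unchanged groups set against those controls gave a median of 0 shared calls in each direction. Those groups hold no real changes, so they cannot show how much the shared controls add where most genes are called. Directly compared, heated WT cells had more HSP30 by 8.84 ± 0.14, BTN2 by 5.65 ± 0.12, SSA4 by 5.41 ± 0.13 and KAR2 by 4.17 ± 0.08 than WT cells in NaCl (log2, SE, n = 3 per group). STL1 was lower in heat by -10.44 ± 0.15, the glucose transporter gene HXT1 by -6.05 ± 0.11, the cell wall mannoprotein gene FIT1 by -5.84 ± 0.14 and the proline permease gene PUT4 by -5.58 ± 0.15. All 28 chaperone genes were higher in heat (28 adjusted over the list alone; adjusted p = 8.17e-22, but adjusted p = 0.0519 with an estimated correlation). Unfolded protein response genes were higher in 12 of 13 cases (12 adjusted over the list alone; adjusted p = 1.31e-07, and adjusted p = 0.00814 with an estimated correlation). Pheromone response genes were lower in 13 of 16 (13 adjusted over the list alone; adjusted p = 5.08e-05, and adjusted p = 0.00814 with an estimated correlation). Osmotic stress genes were lower in 16 of 22 and higher in 3 (16 and 3 adjusted over the list alone; adjusted p = 5.08e-05, but adjusted p = 0.206 with an estimated correlation). In all 4226 genes differed, 2104 higher and 2122 lower in heat, or 1209 and 3025 with library totals alone.

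Unstressed S121A cells expressed several stress and mating genes above WT and iron uptake genes below it. FIG1, which acts in mating, was higher by a log2 fold change of 2.02 ± 0.20 (SE, n = 3 per group), HSP26 by 1.87 ± 0.10, HSP30 by 1.71 ± 0.10, the zinc-regulated ZPS1 by 1.62 ± 0.09, HXT5 by 1.56 ± 0.11 and NCA3 by 1.44 ± 0.09. The iron oxidase gene FET3 (YMR058W, chromosome XIII, 388822 to 390732) was lower by -1.36 ± 0.09. So were the siderophore transporter genes SIT1 by -1.23 ± 0.09 and ENB1 by -1.12 ± 0.08, the dicarboxylic amino acid permease gene DIP5 by -1.02 ± 0.09 and the zinc transporter gene ZRT2 by -0.96 ± 0.08. Of the 20 iron regulon genes 13 were lower and 0 higher, with a median of -0.58, or 1.49-fold (14 lower adjusted over the list alone; adjusted p = 5.77e-09, but adjusted p = 0.0869 with an estimated correlation). Meiosis and sporulation genes were higher in 9 of 20 cases and lower in 0, including SPS100 by 1.16 ± 0.12 and the regulator NDT80 by 1.07 ± 0.17 (11 adjusted over the list alone; adjusted p = 4.98e-06, and adjusted p = 0.0355 with an estimated correlation). Pheromone response genes were higher in 8 of 16 cases, among them FIG2, on chromosome III, at 0.88 ± 0.08, and lower in 3 (8 and 4 adjusted over the list alone; adjusted p = 0.00192, and adjusted p = 0.0488 with an estimated correlation). Their median was 0.44, and -0.03 without chromosome III genes, an alternative chosen after seeing the data in which the list was not called (adjusted p = 0.0815). Alpha-specific and silent mating genes were higher in 6 of 8 cases, including STE3 by 1.01 ± 0.19 (7 adjusted over the list alone; adjusted p = 4.94e-05, but adjusted p = 0.0697 with an estimated correlation). Without chromosome III genes, left out after seeing the data, 2 of 4 were higher with a median of 0.72 (adjusted p = 0.00511). Reads of its members HMRA1 at 0.91 ± 0.20 and HMRA2 at 0.93 ± 0.21 can be shared with the active mating locus.

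Carbon and growth genes also differed without stress. Glycolysis genes were lower in 14 of 17 cases with a median of -0.41, including PDC1 by -0.61 ± 0.09 and PFK2 by -0.54 ± 0.09 (15 adjusted over the list alone; adjusted p = 4.98e-06, but adjusted p = 0.312 with an estimated correlation). Trehalose and glycogen genes were lower in 12 of 17, including GSY1 by -0.78 ± 0.09 (12 adjusted over the list alone; adjusted p = 4.98e-06, but adjusted p = 0.288 with an estimated correlation). Ergosterol synthesis genes were lower in 14 of 25, including ERG4 by -0.63 ± 0.10 (15 adjusted over the list alone; adjusted p = 8.71e-05, but adjusted p = 0.295 with an estimated correlation). Cell wall genes were lower in 11 of 20 and higher in 2, including SED1 by -0.66 ± 0.09 (15 and 2 adjusted over the list alone; adjusted p = 0.000298, but adjusted p = 0.295 with an estimated correlation). G1/S genes were lower in 9 of 20, including CLN2 by -0.51 ± 0.10, or -0.35 with library totals alone, where CLN2 did not pass at an adjusted p of 0.0524 (10 adjusted over the list alone; adjusted p = 9.16e-05, but adjusted p = 0.0697 with an estimated correlation). G2/M genes were lower in 4 of 16 and higher in 1 (6 and 1 adjusted over the list alone; adjusted p = 0.033, but adjusted p = 0.443 with an estimated correlation). The a-specific genes were lower in 5 of 8 (5 adjusted over the list alone; adjusted p = 0.0281, but adjusted p = 0.295 with an estimated correlation). Osmotic stress genes were higher in 11 of 22 and lower in 4, including NQM1 by 1.19 ± 0.09 (12 and 4 adjusted over the list alone; adjusted p = 0.000672, but adjusted p = 0.295 with an estimated correlation). General stress genes were higher in 11 of 25 and lower in 5, including DDR2 by 1.16 ± 0.10 (13 and 5 adjusted over the list alone; adjusted p = 0.00224, but adjusted p = 0.424 with an estimated correlation). Chaperones were higher in 9 of 28 and lower in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.00851, but adjusted p = 0.589 with an estimated correlation). Scaling moved these medians. Over 3 other scalings they ran from -0.42 to -0.24 for glycolysis, -0.34 to -0.17 for trehalose and glycogen, -0.26 to -0.08 for ergosterol and -0.30 to -0.12 for cell wall genes. For G1/S, G2/M and a-specific genes they ran from -0.24 to -0.07, -0.21 to -0.03 and -0.30 to -0.13. For osmotic stress, general stress and chaperone genes they ran from 0.27 to 0.45, 0.27 to 0.44 and 0.05 to 0.22. Ribosome biogenesis genes were not called as a list before stress (4 of 62 higher, 3 adjusted over the list alone; adjusted p = 0.157), and neither were cytosolic ribosomal proteins (5 higher and 4 lower of 138, 2 and 1 adjusted over the list alone; adjusted p = 0.163).

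Across all genes, 1480 differed between unstressed S121A and WT, 579 higher and 901 lower, with 109 and 5 at least 2-fold different. The split was 1144 higher and 232 lower with library totals alone, a scaling that moved the median over all genes to 0.15. The stricter filter gave 512 higher and 501 lower. The count was 2543 with the compared libraries alone (1323 higher and 1220 lower), 927 without WT no stress replicate 1 and 869 without S121A no stress replicate 2.

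Genes on chromosome III were higher in S121A as a block. Of 164 tested genes matched to coordinates on it 142 were called higher and 0 lower without stress, 147 and 0 under NaCl, and 138 and 1 under heat. Another 16 tested features have systematic names of chromosome III but no match in the reference table and are not in these counts. Of these 9, 8 and 7 were called higher in the same order and 0 lower. Relative to the other chromosomes its median level was higher in S121A by 0.61 on the log2 scale without stress (SD over the 3 libraries 0.016 in S121A and 0.027 in WT), by 0.66 under NaCl and by 0.71 under heat. Over the conditions the ratio was 1.58, with an exact permutation p = 0.00025, the smallest that 8000 arrangements can give, and an adjusted p = 0.000571. Chromosome VIII was higher by 0.13, 0.12 and 0.20 in the same order, a ratio of 1.11. Chromosomes IV, VI, VIII, X, XIII and XV reached the same smallest p of 0.00025 by the exact permutation test as chromosome III, so that p is not particular to III. Their ratios other than that of VIII lay between 0.965 and 1.04. HSP30, PWP2, BUD23, FIG2, FUS1, LEU2, HMRA1 and HMRA2, named here for their differences between genotypes, lie on chromosome III, where reads of the inserted LEU2 marker are counted too. Of 241 genes called higher in S121A in all 3 conditions 120 are matched to chromosome III and 5 more are named as lying there, against 0 matched of the 78 called lower in all 3. Effects of this chromosome III difference on genes elsewhere cannot be told apart from those of S121A here. Leaving out chromosome III genes does not remove such effects.

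**Figure D1:**
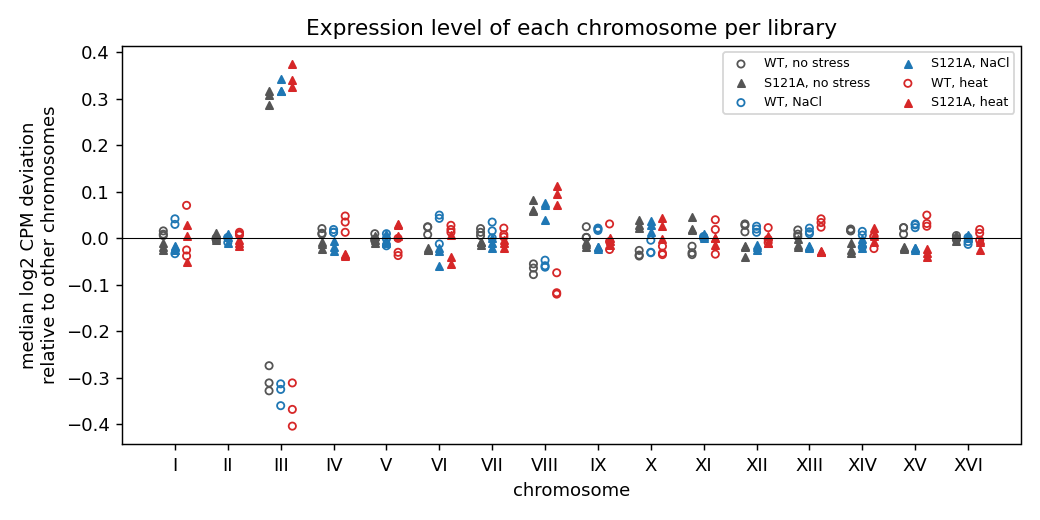
Median log2 CPM deviation of the genes of each chromosome relative to the other chromosomes, 1 point per library, with WT as open circles and S121A as filled triangles, and colours for the conditions. Chromosome III parts the genotypes by 0.61 to 0.71 in the 3 conditions.

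Under NaCl, S121A cells held more ribosome biogenesis RNA than WT cells in the same salt. Among genes meeting the naming rule NCA3 (YJL116C, chromosome X, 193860 to 194873) differed most, by a log2 fold change of 2.78 ± 0.10 (SE, n = 3 per group). A feature outside the rule was called with a larger difference, 4.88. The ribosome biogenesis genes PWP2 by 1.81 ± 0.12, HCA4 by 1.68 ± 0.10 and BUD23 by 1.51 ± 0.15 were higher. The uracil permease gene FUR4 was higher by 1.67 ± 0.09. FRE3, a siderophore reductase gene, was lower by -1.21 ± 0.09, FET3 by -1.01 ± 0.09, ZRT2 by -0.90 ± 0.08 and the lactate dehydrogenase gene CYB2 by -0.82 ± 0.08. Ribosome biogenesis genes were higher in 58 of 62 cases with a median of 0.99, or 1.98-fold (61 adjusted over the list alone; adjusted p = 9.98e-32, and adjusted p = 0.0272 with an estimated correlation). Pheromone response genes were higher in 8 of 16, including PRM3 by 2.21 ± 0.37 and FIG1 by 1.95 ± 0.23 (8 adjusted over the list alone; adjusted p = 0.00125, and adjusted p = 0.0272 with an estimated correlation). Without chromosome III genes 5 of 13 were higher with a median of 0.11 (adjusted p = 0.0265), against 0.27 with them. Chaperones were higher in 20 of 28, including BTN2 by 1.28 ± 0.10 and YDJ1 by 0.83 ± 0.08 (20 adjusted over the list alone; adjusted p = 1.44e-10, but adjusted p = 0.245 with an estimated correlation). Iron regulon genes were lower in 10 of 20 (12 adjusted over the list alone; adjusted p = 3.15e-06, but adjusted p = 0.245 with an estimated correlation). Osmotic stress genes were lower in 6 of 22 and higher in 1, including GCY1 by -0.56 ± 0.08 (6 and 2 adjusted over the list alone; adjusted p = 0.00612, but adjusted p = 0.613 with an estimated correlation). Glucose-repressed genes were higher in 7 of 20, including SUC2 by 0.74 ± 0.10 and the paralogs HXT6 and HXT7, whose reads cannot be told apart here (8 adjusted over the list alone; adjusted p = 0.00314, but adjusted p = 0.613 with an estimated correlation). In all 1519 genes differed, 931 higher and 588 lower, with 178 and 6 at least 2-fold different.

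After heat ribosome biogenesis genes were again higher in S121A than in WT. HCA4 (YJL033W, chromosome X, 383837 to 386149), an RNA helicase gene of ribosome assembly, was higher in S121A by a log2 fold change of 3.09 ± 0.12 (SE, n = 3 per group), NCA3 by 2.15 ± 0.10, the RNA polymerase I subunit gene RPA190 by 1.78 ± 0.13, GAR1 by 1.67 ± 0.09 and the export adapter gene NMD3 by 1.67 ± 0.09. ZRT2 was lower by -1.05 ± 0.08, AIM44 by -1.01 ± 0.11 and the cohesin gene SMC3 by -0.87 ± 0.13. Ribosome biogenesis genes were higher in 60 of 62 cases with a median of 1.27, or 2.41-fold (60 adjusted over the list alone; adjusted p = 2.17e-32, and adjusted p = 0.0134 with an estimated correlation). Unfolded protein response genes were lower in 10 of 13 with a median of -0.42, including MPD1 by -0.82 ± 0.09, JEM1 by -0.81 ± 0.09 and LHS1 by -0.75 ± 0.06 (11 lower and 1 higher adjusted over the list alone; adjusted p = 9.18e-07, and adjusted p = 0.0134 with an estimated correlation). Pheromone response genes were higher in 10 of 16 and lower in 1, including FIG1 by 1.68 ± 0.23 and FUS1, on chromosome III, by 1.07 ± 0.09 (11 and 1 adjusted over the list alone; adjusted p = 0.000189, and adjusted p = 0.0134 with an estimated correlation). Cytosolic ribosomal protein genes were higher in 87 of 138 with a median of 0.34 (96 adjusted over the list alone; adjusted p = 5.55e-14, but adjusted p = 0.397 with an estimated correlation). Subtelomeric families were higher in 22 of 41, including PAU24 by 1.46 ± 0.16, in families whose members share reads (24 adjusted over the list alone; adjusted p = 1.2e-05, but adjusted p = 0.149 with an estimated correlation). Amino acid biosynthesis genes were higher in 24 of 42, including ILV3 by 1.21 ± 0.08 (25 higher and 1 lower adjusted over the list alone; adjusted p = 3.2e-07, but adjusted p = 0.397 with an estimated correlation). Glucose-repressed genes were higher in 14 of 20, including SUC2 by 0.94 ± 0.10 (16 adjusted over the list alone; adjusted p = 0.000163, but adjusted p = 0.397 with an estimated correlation).

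Smaller groups also differed in heat. Methionine and sulfur genes were higher in 13 of 24 and lower in 2, including STR3 by 1.36 ± 0.12 (14 and 3 adjusted over the list alone; adjusted p = 0.00254, but adjusted p = 0.397 with an estimated correlation). Daughter and early G1 genes were lower in 8 of 15 and higher in 1, including the replication licensing gene CDC6 by -0.85 ± 0.11 (8 and 1 adjusted over the list alone; adjusted p = 0.00103, but adjusted p = 0.397 with an estimated correlation). Centromere and spindle checkpoint genes were lower in 9 of 20 and higher in 1, including the cohesin gene MCD1 by -0.60 ± 0.09 (10 and 1 adjusted over the list alone; adjusted p = 0.00254, but adjusted p = 0.397 with an estimated correlation). Cell wall genes were lower in 8 of 20 and higher in 2, including KDX1 by -0.87 ± 0.08 (9 and 2 adjusted over the list alone; adjusted p = 0.00856, but adjusted p = 0.489 with an estimated correlation). Osmotic stress genes were lower in 7 of 22 and higher in 2, including ALD3 by -0.58 ± 0.07 (11 and 4 adjusted over the list alone; adjusted p = 0.043, but adjusted p = 0.546 with an estimated correlation). Iron regulon genes were not called as a list (10 higher and 4 lower of 20, 10 and 4 adjusted over the list alone; adjusted p = 0.0643), with FTR1 higher by 0.81 ± 0.09. They were called without chromosome III genes (adjusted p = 0.0349), a test run with the preset correlation alone. In all 2156 genes differed, 1250 higher and 906 lower, with 253 and 12 at least 2-fold different. The split was 1107 higher and 1139 lower with library totals alone, and 1218 genes differed when the heated libraries were modelled alone (839 higher and 379 lower).

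The stress lists also moved in S121A cells, and the response differences given after them test how far these responses depart from those of WT. Under NaCl all 22 osmotic stress genes rose with a median of 4.32 (22 adjusted over the list alone; adjusted p = 9.19e-16, and adjusted p = 0.0261 with an estimated correlation), including STL1 by 12.08 ± 0.16 (log2, SE, n = 3 per group) and TKL2 by 7.12 ± 0.11. In the same cells all 62 ribosome biogenesis genes fell with a median of -2.99 (62 adjusted over the list alone; adjusted p = 1.17e-24, and adjusted p = 0.0302 with an estimated correlation), including NOG2 by -4.86 ± 0.12. Under heat all 28 chaperones rose with a median of 4.04 (28 adjusted over the list alone; adjusted p = 1.11e-14, but adjusted p = 0.0737 with an estimated correlation), including SSA4 by 7.72 ± 0.15 and HSP26 by 7.24 ± 0.12. All 62 ribosome biogenesis genes fell in heat with a median of -4.10 (62 adjusted over the list alone; adjusted p = 6.18e-22, but adjusted p = 0.053 with an estimated correlation), including NOP7 by -4.77 ± 0.09. General stress and G1/S genes under NaCl (adjusted p = 0.0302 and 0.0261) and pheromone response genes under heat (adjusted p = 0.0243) were the other lists called in S121A with an estimated correlation. In S121A 4543 genes changed under NaCl, 2287 higher and 2256 lower, and 5115 under heat, 2579 higher and 2536 lower. With library totals alone the splits were 1572 and 3139 under NaCl and 1372 and 3899 under heat.

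The response difference tests whether S121A cells responded otherwise than WT cells to the same stress. Under NaCl the fall of ribosome biogenesis genes was smaller in S121A. Among genes meeting the naming rule SYO1 differed most, by 2.38 ± 0.28 on the log2 scale (SE, n = 3 per group), with responses of -6.59 in WT and -4.20 in S121A. RRS1 differed by 1.78 ± 0.19 and PUF6 by 1.73 ± 0.26, and FUR4 differed by 1.85 ± 0.12, at -0.31 ± 0.08 in WT and 1.53 ± 0.09 in S121A. HXT5, HSP26 and NQM1 rose less in S121A, by differences of -1.79 ± 0.15, -1.47 ± 0.13 and -1.44 ± 0.12. These 3 genes were already higher in unstressed S121A. Of 62 ribosome biogenesis genes 49 had a positive difference that passed, with a median of 0.88 (58 adjusted over the list alone; adjusted p = 5.73e-31, and adjusted p = 0.0475 with an estimated correlation). Osmotic stress genes had a negative difference in 10 of 22 and a positive one in 1 (13 and 2 adjusted over the list alone; adjusted p = 8.82e-09, but adjusted p = 0.113 with an estimated correlation), including TKL2 at -1.29 ± 0.13. Of 30 lists 12 were called by the preset test and 1 also with an estimated correlation, and only some are given here. General stress genes had medians of -0.39 to -0.22 over 3 other scalings. In all 534 genes differed, 436 positive and 98 negative. The split was 215 and 257 with library totals alone and 433 and 246 with the compared groups alone.

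The heat response also differed between the genotypes. HCA4 had a difference of 2.92 ± 0.14 (log2, SE, n = 3 per group), at -5.35 ± 0.11 in WT and -2.43 ± 0.09 in S121A. The ribosome biogenesis genes ERB1, YTM1 and UTP14 differed by 2.05 ± 0.19, 2.03 ± 0.17 and 2.03 ± 0.22. HSP26 had a difference of -1.89 ± 0.13, HXT5 of -1.73 ± 0.15, SIP18 of -1.64 ± 0.31 and the membrane stress gene HSP12 of -1.57 ± 0.22. HSP26 and HXT5 were already higher in unstressed S121A by 1.87 ± 0.10 and 1.56 ± 0.11, about the size of their response differences. Of 62 ribosome biogenesis genes 52 had a positive difference that passed, with a median of 1.12 (59 adjusted over the list alone; adjusted p = 7.81e-28, and adjusted p = 0.035 with an estimated correlation). Unfolded protein response genes had a negative difference in 6 of 13, including DER1 at -0.89 ± 0.16 and SIL1 at -0.88 ± 0.09 (6 adjusted over the list alone; adjusted p = 1.71e-05, and adjusted p = 0.035 with an estimated correlation). Meiosis and sporulation genes had a negative difference in 7 of 20 (8 adjusted over the list alone; adjusted p = 6.53e-05, and adjusted p = 0.0393 with an estimated correlation). Over 3 other scalings the median of meiosis genes in S121A against WT was 0.45 to 0.63 without stress and -0.01 to 0.06 under heat. Iron regulon genes had a positive difference in 15 of 20 and a negative one in 1, including SIT1 at 1.87 ± 0.14 and FET3 at 1.45 ± 0.13 (18 and 1 adjusted over the list alone; adjusted p = 2.41e-09, but adjusted p = 0.112 with an estimated correlation). SIT1 and FET3 were already lower in unstressed S121A, by -1.23 ± 0.09 and -1.36 ± 0.09. Amino acid biosynthesis genes had a positive difference in 28 of 42, including LEU9 at 1.16 ± 0.12 (32 adjusted over the list alone; adjusted p = 1.25e-10, but adjusted p = 0.213 with an estimated correlation). With library totals alone the medians of these lists were 0.22 for amino acid biosynthesis, -0.48 for the unfolded protein response and -0.66 for meiosis, against 0.44, -0.27 and -0.43. Of 30 lists 22 were called by the preset test and 3 also with an estimated correlation, and only some are given here. General stress genes had medians of -0.65 to -0.39 over 3 other scalings. Against WT their medians in S121A were 0.27 to 0.44 without stress and -0.14 to -0.05 under heat. In all 1445 genes differed, 992 positive and 453 negative, or 503 and 1229 with library totals alone. The count was 934 without S121A no stress replicate 2, 2340 without WT heat replicate 1 and 939 without WT heat replicate 2.

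**Figure D2:**
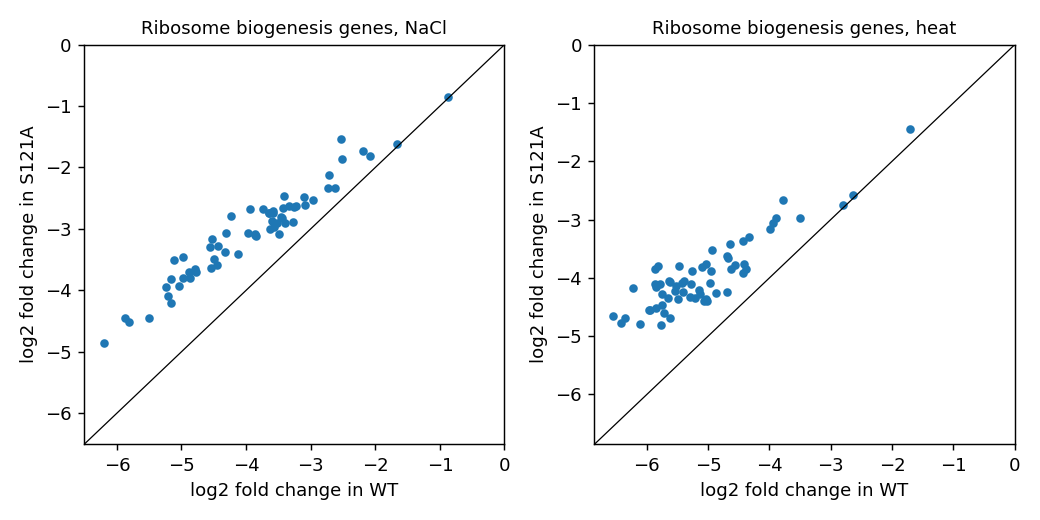
Log2 fold change of the 62 ribosome biogenesis genes under each stress in WT (horizontal) and in S121A (vertical), 1 point per gene from 3 libraries per group, with a line at equal responses. In both stresses 62 of 62 genes lie above the line, a smaller fall in S121A.

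Scores over all stress-responsive genes give the size of the difference in the whole programme, with an SE formed from the spread of the 3 libraries within each of 4 groups. The 945 NaCl-induced genes rose by a mean of 1.83 in WT and 1.76 in S121A, a difference of -0.08 with an SE of 0.011 (n = 3, exact permutation p = 0.005, the smallest that 400 arrangements can give). It was -0.225 with library totals alone and -0.119 with the stricter filter, each with an exact permutation p of 0.005. The 2 arrangements that reached -0.08 kept the real stressed split or its mirror, so that p too was set by the unstressed splits. S121A differed from WT by 0.024 without stress and by -0.054 under NaCl, opposite signs that make this p small. It is no measure of the size of the effect either. The 884 NaCl-repressed genes changed by -1.90 in WT and -1.59 in S121A, a difference of 0.31 with an SE of 0.025 (n = 3, exact permutation p = 0.045). All 18 arrangements that reached this difference kept the real split of the stressed libraries or its mirror, so the p was set by the 20 splits of the unstressed libraries and could be at most 0.1 among these. It is therefore no measure of the size of the effect, on either side of 0.05. The difference was 0.324 with the stricter filter (exact permutation p = 0.1), 0.518 for genes changed at least 4-fold (p = 0.095), 0.362 with a pseudocount of 0.25 (p = 0.08) and 0.3 without chromosome III genes (p = 0.07). It was 0.308, 0.303 and 0.329 in the 3 of 12 cases with 1 library left out in which p was 0.05 or more (0.05, 0.08 and 0.05). Only with library totals alone was it smaller by more than 1.5 times, at 0.117 (exact permutation p = 0.455). The 1243 heat-induced genes differed by -0.03 with an SE of 0.033 (n = 3, exact permutation p = 0.365), which did not pass. With library totals alone the difference was -0.25 (exact permutation p = 0.01). The 1330 heat-repressed genes differed by 0.28 with an SE of 0.025 (n = 3, exact permutation p = 0.095). Here all 38 arrangements that reached it kept the real stressed split or its mirror, so this p does not decide either. The difference turned to -0.01 with library totals alone.

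**Figure D3:**
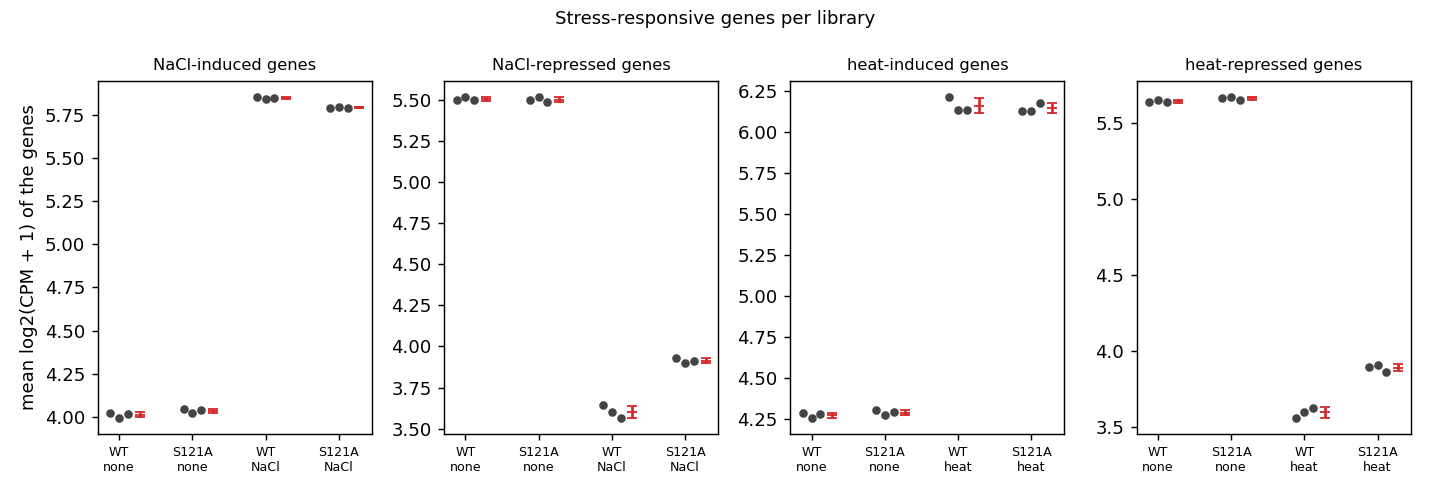
Mean log2(CPM + 1) of the stress-responsive genes in each library (grey points), with the group mean and SD of 3 libraries in red, for the sets chosen by the average response of both genotypes. NaCl-repressed genes lie higher in stressed S121A than in stressed WT, a response difference of 0.31.

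The difference between S121A and WT was partly shared by the conditions. Across genes, which are not independent replicates, its log2 fold changes correlated with r = 0.541 between no stress and NaCl, 0.387 between no stress and heat, and 0.554 between NaCl and heat. Without chromosome III genes r was 0.495, 0.335 and 0.514, and with the stricter filter the value for no stress and heat was 0.242. Called higher under both NaCl and heat were 634 genes and lower 175, against 182 and 83.3 if independent, with 45 opposite. For no stress and heat these were 328 and 172, against 113 and 128, with 135 opposite. For no stress and NaCl they were 319 and 265, against 84.3 and 82.8, with 40 opposite. NCA3, FIG1 and ZPS1 were among the genes higher in all 3 conditions. ZPS1 differed by 1.62 ± 0.09 without stress and 1.71 ± 0.09 under NaCl.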

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

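Tests chosen after the results were seen are, for chromosome III, the one on genes away from the chromosome's ends and the one on 10 parts of the chromosome, for ribosome biogenesis genes the one on a response scaled down alike, and the requirement of equal shares in the test on unstressed RNA. The tests on GC content, scaling, share of unstressed RNA and read-through were written before their results. Under the requirement as first written, unstressed RNA would have fitted the heat result as well as the NaCl result.

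The NaCl response differed between genotypes for 534 genes and the heat response for 1445, by a test of the difference itself. When genotype labels were redrawn within each condition, 1 of 100 draws, the real one, gave as many in each stress. The highest others were 175 and 615. This argues against counts that arise with no genotype difference in any condition. The redrawn groups mixed genotypes that differ without stress too, which widens their spread, so the draws cannot test the response difference itself. Among single genes under NaCl the differences on the log2 scale were 2.38 for SYO1, 1.85 for FUR4, 1.78 for RRS1, 1.73 for PUF6 and 1.69 for YGR067C. On the other side they were -1.79 for HXT5, -1.47 for HSP26, -1.47 for YNL194C, -1.44 for NQM1 and -1.42 for SPG4. Under heat they were 2.92 for HCA4, 2.05 for ERB1, 2.03 for SYO1, 2.03 for YTM1 and 2.03 for UTP14. They were -1.89 for HSP26, -1.73 for HXT5, -1.64 for SIP18, -1.62 for YPT53 and -1.57 for HSP12. HSP26, HXT5 and NQM1 were already higher in unstressed S121A, by 1.87, 1.56 and 1.19.

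For the comparisons of 3 libraries with 3, only 10 splits exist, which is too few for a share under 0.05. In each of them 1 split, the real one, gave the highest count. The real count and the highest other were 1480 and 0 for S121A against WT without stress, 1519 and 0 under NaCl, 2156 and 203 under heat, 4706 and 0 for NaCl in WT, 5107 and 0 for heat in WT, 4543 and 0 for NaCl in S121A, 5115 and 0 for heat in S121A, and 4226 and 0 for heat against NaCl. Under NaCl the replicate numbers may pair the S121A and WT libraries, and splits that part the same-numbered libraries as the real one does were among those with 0 calls.

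Chromosome III genes were higher in S121A in all 3 conditions. After adjustment for GC content and gene length, fitted on the other chromosomes, the lowest median over the conditions was 0.627, which argues against such a bias as the whole cause. In the 97 genes over 50 kb from both ends the lowest median was 0.47 (bootstrap interval 0.43 to 0.59), which argues against loss of silencing at the ends and the mating loci as the whole cause. An extra copy of the chromosome in S121A cells stays open: each of 10 parts had a median from 0.385 to 0.81, above a minimum set after these values were seen, which decides nothing. With 2 copies for 1 in every cell and RNA in proportion it would be near 1, against at most 0.67 for the median log2 fold change of its genes (bootstrap interval 0.61 to 0.71) and 0.709 relative to other chromosomes, and no DNA was measured. A smaller ratio of copies, such as 3 for 2, copies in part of the cells or less RNA per copy would give a lower value. None of these was compared with the data, so the shortfall from 1 does not speak against an extra copy.

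Ribosome biogenesis genes were higher in stressed S121A. Other scalings left the lowest medians at 0.97 under NaCl and 1.21 under heat, which argues against scaling. With TMM the response ratio of induced genes exceeded that of the list by 0.175 and 0.209, which argues against a response scaled down alike. That ratio was taken with TMM alone and sets a mean score beside a median of fold changes. With library totals alone the induced genes lagged more in S121A, so a response scaled down alike stays open under that scaling. Unstressed RNA in the stressed S121A libraries stays open under NaCl, where the share needed by other repressed genes (6.54%) was 1.138 times that of the list (5.75%, interval of the ratio 0.95 to 1.4), although 31 ribosomal protein genes at least 2-fold lower in WT would need 11.7%. Under heat that ratio was 1.448 (interval 1.28 to 1.72, shares of 5.16% and 3.56%), so 1 share for all genes is not enough there, while part of the difference could come from it. The list's share predicts a mean log2 fall of -0.054 in NaCl-induced genes and -0.034 in heat-induced genes. Stressed S121A differed from stressed WT by -0.054 and -0.016 in these genes. A weaker repression, a slower loss of RNA or a later response in S121A were not separated from unstressed RNA by these data.

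HCA4 was higher in heated S121A than the other ribosome biogenesis genes. It lies 462 bp downstream of the heat-induced KAR2 on the same strand, and its reads could include transcripts that run past KAR2. Across 89 genes downstream of heat-induced genes the median heat response difference exceeded that of 2262 other neighbours by 0.083 (bootstrap interval -0.03 to 0.21). This argues against an increase of read-through in S121A large enough to lift these genes in general. They were taken whatever their own level, so an increase visible only in weakly expressed ones is not excluded. Read-through at this locus alone was not tested.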

How the results depend on the processing

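Only the alternative without chromosome III genes was chosen after seeing the data. Of 3795 alternative values of 229 named gene results 3779 stayed the same, 11 were weaker, 2 stronger and 3 reversed. For a gene, the same means that its sign and its call were kept. Many of these genes were named for large changes with a small adjusted p, which favours keeping them. The changed ones belong to HTA1, HTB1, HIS3, LEU2, TRP1, LYS2 and CLN2. With library totals alone the difference between unstressed S121A and WT reversed to 0.108 for HTB1, 0.015 for LEU2 and 0.078 for TRP1, none of which passed (adjusted p of 0.42, 0.868 and 0.486). That scaling raised the median over all genes in this comparison. Of 356 alternative values of the counts, scores, similarities and list tests, 322 stayed the same, 28 were weaker, 3 stronger, 2 moved and 1 reversed. Counts within 1.5 times were taken as the same, even where their split turned. Without stress that split was 1144 higher and 232 lower with library totals alone, against 579 and 901. Causes were not tested except where named. With an adjusted p under 0.01, a stricter threshold by construction, the counts for S121A against WT were 760, 953 and 1323 (no stress, NaCl, heat) and for the response differences 276 (NaCl) and 754 (heat). With the compared groups alone they were 2543 without stress, 1296 under NaCl and 1218 in heat. The order of no stress and heat was the reverse with all groups in 1 fit, at 1480 and 2156. That fit shares its spread over the groups. Replicates within a group differed by a chi-square per degree of freedom of 16.4 to 26.9 without stress and 22.7 to 83.9 in heat. Whether this unequal spread is the cause was not tested. With an estimated correlation in place of the preset one, the lists called were 2, 2 and 3 for S121A against WT (no stress, NaCl, heat; preset 15, 9 and 12), 4 and 5 for NaCl and heat in WT (15 and 18), 4 and 1 in S121A (15 and 16), 2 for heat against NaCl (14), and 1 and 3 for the NaCl and heat response differences (12 and 22). The cause was not tested. The score of NaCl-repressed genes was 0.362 (p = 0.08) with a pseudocount of 0.25, 0.518 (p = 0.095) for genes changed at least 4-fold, 0.117 (p = 0.455) with library totals alone, 0.324 (p = 0.1) with the stricter filter and 0.3 (p = 0.07) without chromosome III genes, all by the exact permutation test. That p is set by the split of the unstressed libraries, and only the value with library totals alone is less than 0.312 by more than 1.5 times, for which the cause was not tested. With library totals alone the score was -0.225 for NaCl-induced genes (exact permutation p = 0.005), -0.247 for heat-induced genes (exact permutation p = 0.01) and reversed to -0.013 for heat-repressed genes (exact permutation p = 0.9). That scaling moved the median over all genes to 0.15 for S121A against WT without stress, -0.14 and -0.37 for NaCl and heat in WT, -0.30 and -0.63 in S121A, -0.26 for heat against NaCl, and -0.12 and -0.17 for the NaCl and heat response differences, which is the shift to set against its splits. The similarity of no stress and heat was 0.242 with the stricter filter.

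Leaving out 1 library at a time gave 869 to 1154 genes for S121A against WT without stress, 934 to 2340 for the heat response difference, 0.287 to 0.329 for the score of NaCl-repressed genes (highest exact permutation p = 0.08) and 0.453 to 0.574 for the similarity of NaCl and heat. The replicate block changed no call beyond 1.5 times, with 1519, 1586 and 2197 genes for S121A against WT and 556 and 1446 for the response differences. With it, 1 list of the heat response difference was no longer called (21 against 22). Outside S121A against WT under NaCl the same-numbered libraries did not all exceed the correlation set for pairing. In the simulation at this depth, genes changed 1.5-fold were missed more often in the response differences, where 52.2% (NaCl) and 43.3% (heat) were recovered.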

Other observations

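No test in this part was run beyond those already given. DNA damage response genes were not called as a list in S121A against WT without stress (1 of 20 higher and 2 lower, 1 and 2 adjusted over the list alone; adjusted p = 0.286). Under NaCl they were not called either (1 and 3, 1 and 1 adjusted over the list alone; adjusted p = 0.482), nor under heat (3 and 6, 3 and 6 adjusted over the list alone; adjusted p = 0.0971). RNR1, which makes DNA precursors, was higher in heated S121A by 0.66 ± 0.10 (log2, SE, n = 3 per group). The phosphate regulon was not called in these comparisons (adjusted p of 0.207, 0.77 and 0.248), while the acid phosphatase gene PHO5 was higher by 0.56 ± 0.09, 0.48 ± 0.09 and 0.99 ± 0.09 in the same order.

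Iron regulon genes had a median difference of -0.58 without stress, -0.25 under NaCl and 0.28 under heat. SIT1 differed by -1.23 ± 0.09 without stress and by 0.63 ± 0.10 under heat. In heated WT cells SIT1 fell by 3.29 on the log2 scale.

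HIS3 was lower in unstressed S121A by -0.98 ± 0.10, and by -0.81 for HIS3 with library totals alone. HTA1 and HTB1 from the same plasmid differed by 0.11 ± 0.10 and -0.06 ± 0.09 there, neither passing, and were lower in S121A under NaCl by -0.37 ± 0.10 and -0.46 ± 0.09.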
